A study of Mus with 51 samples.

How the data were processed

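Poly-adenylated RNA of sorted lymph node CD4 T cells was sequenced as paired reads in 51 libraries of 18 groups, which are 6 sorting phenotypes at 3 times. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, aligned to mm10 with STAR 2.6.1c and assigned to genes with HTSeq 0.9.1. The deposited matrix of raw counts was used for every test. It has 34923 features named by gene symbol, 0 without a name, and 38 with a repeated symbol, and 0 of its sample columns were left unused. A second deposited table, headed as TPM per its file name, holds columns that sum to 9986 to 9996, and its values are proportional to the counts within a library once gene length is taken into account (largest coefficient of variation 0.05%). It served only for this check. Each feature carries an identifier beside its symbol, and no coordinates are stated here. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 4.17 to 21.65, so no pair of columns within a group is a copy; columns of different groups were not compared in this way.

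Total counts per library ran from 29030 to 10278776. Libraries were normalized with TMM, genes were kept with filterByExpr by group (17211 genes), and a quasi-likelihood model with robust estimation was fitted to all 51 libraries with 1 coefficient per group (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Differences were tested two-sided with the quasi-likelihood F test and adjusted over all genes tested by Benjamini and Hochberg at a false discovery rate of 0.05. Unchanged genes would on average have an unadjusted p under 0.05 in a share of 0.05 of the 17211 genes. A count well below that marks a conservative test. A comparison over times is the mean of the 3 differences within time, and the test of whether GP acts differently in activated cells is the difference between such means. A gene absent from a whole group is given as a fold of at least the value over 3 counts in that group. Precision differed between comparisons: among 4613 genes above 50 CPM the median SE of a log2 fold change was 0.168 for GP against NP at 1 h, 0.207 at 6 h, where both groups hold 2 libraries, and 0.169 at 24 h. It was 0.195, 0.168 and 0.167 for MCC+GP CD69-hi against MCC CD69-hi.

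Gene lists were tested with camera (limma) at its preset correlation of 0.01, adjusted over the 532 tests of 28 lists in the comparisons set in advance. Of these, 188 passed; 47 of the 188 also passed with a correlation estimated from the data and 117 with fry, which asks only whether a list moves to one side on balance. Lists in the 6 comparisons added later were adjusted among themselves. The lists were written before the data were examined: early TCR response, ERK feedback and targets, calcium and NFAT targets, NF-kB targets, cytokines and chemokines, activation and costimulatory receptors, inhibitory receptors and anergy, naive and quiescence, TCR complex and proximal signalling, cell cycle, ribosome biogenesis, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid uptake with ATF4 and one-carbon genes, heat shock and stress, apoptosis, type I interferon response, interferon gamma response, T helper 1, T helper 2, follicular helper T, regulatory T, and, for other cells, B cells, MHC class II presentation, myeloid and dendritic cells, NK and CD8 T cells, and stroma with endothelium and erythroid cells. The symbols Atp5f1a, Atp5f1b, Ccl21a, Ccl19, Ifi206, Ifi208, Ifi209 and Ifi213 were absent from the table.

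The comparisons, the model, the alternatives to it and the rule for naming genes were also set before the data were examined. By that rule, a comparison names a fixed panel (Cd69, Nr4a1, Egr1, Egr2, Egr3, Myc, Irf4, Il2, Il2ra, Cd5, Klf2, Mki67), up to 6 rising and 6 falling genes with the largest change among those past the threshold with at least 5 CPM and no overlap between libraries, and up to 4 members per list. Only part of the genes it names is described. Elmo2 in the mean over times lies outside the rule, and was named because it and Pgm2 were the only genes called there, after their values were seen.

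The alternatives set at that point were RLE size factors, no filter on low counts, DESeq2 1.42.0, only the compared groups in the fit, a replicate block by plate round (the plate-round block), and each library left out in turn. DESeq2 replaced its parametric dispersion trend, which did not capture the data, with a local regression. Fits with a library left out kept the genes and the dispersion trend of the complete fit, and re-estimated the size factors and each gene's dispersion. Further alternatives were added after results had been seen: a plate-round-within-time block, only the compared groups with a plate-round block, B-cell RNA as a covariate, the 3 shallowest libraries (MCC+GP CD69-lo at 24 h) left out, NP 6 h and NP 24 h without their first library, a separate spread for each group, the MCC CD69-hi libraries of 1 h thinned, and the mean of 1 and 6 h only.

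The labels number no replicates, so libraries are numbered by the order of their accessions. The titles hold a plate well, and wells fall into rounds of filling that could pair libraries of different groups. Deviations from the group means had a median correlation of 0.327 across genes over 110 pairs of the same time and round (negative 0.047 to 0.777, 92 over 0.1), and of negative 0.131 over 253 pairs of the same time and another round; genes are not independent replicates. In each comparison with 3 such pairs, all 3 were over 0.1. Comparisons with fewer pairs were not decided, and for MCC+GP CD69-lo against MCC CD69-lo at 24 h the 2 correlations were 0.011 and 0.05.

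The pipeline was tested on simulated counts drawn from the means, depths and dispersions of the real libraries, with 200 of 15981 genes changed by known folds. Each gene had the same dispersion in all groups, and changed genes were drawn from the more abundant ones. Figures and label tables were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.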

Results

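The series measured poly-adenylated RNA of CD4 T cells from lymph nodes of 5C.C7 mice, a Rag2-deficient strain whose T cells carry a transgenic receptor for a moth cytochrome c peptide (MCC). Cells were kept without peptide (NP), with GP, which is the self-peptide of the design, with MCC, or with MCC and GP together (MCC+GP), and were collected at 1, 6 or 24 h. MCC and MCC+GP cells were sorted into CD69-high and CD69-low fractions, written here as CD69-hi and CD69-lo. CD69 is a surface receptor that appears within hours of T cell receptor (TCR) signalling. The 51 libraries fall into 18 groups. NP 6 h, GP 6 h and MCC CD69-lo 6 h hold 2 libraries each, and the other 15 groups hold 3. Total counts per library ran from 29030 to 10278776 with a median of 5436653. NP libraries held 4635680 to 6953485 counts and GP libraries 4944475 to 5898008. MCC CD69-hi libraries held 852129 to 3346959 counts at 1 h, 5961902 to 8029952 at 6 h and 7551281 to 8642984 at 24 h. MCC+GP CD69-hi libraries held 930161 to 1105292, 5227459 to 7477764 and 5726942 to 10278776 at these times. In MCC CD69-lo the totals were 4404348 to 6106519 at 1 h, 5225827 to 5890052 at 6 h and 941304 to 2870776 at 24 h. In MCC+GP CD69-lo they were 5557021 to 6285828 at 1 h and 3169914 to 5874039 at 6 h. The 3 MCC+GP CD69-lo libraries of 24 h held 237390, 29030 and 301455 counts. The labels do not say that replicates come from separate animals, so the adjusted p-values measure only the spread between these samples. Floors cover counting error only. Intervals are built from the SE of the fit, so they too measure only the spread between these samples. Values below are CPM (normalized counts of a gene per 1e6 counts of its library), given as mean ± SD over the libraries of a group, and log2 fold changes ± SE.

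Because cells were sorted on CD69, Cd69 RNA comes first. At 1 h Cd69 stood at 220 ± 105 CPM in NP (n = 3), 1120 ± 414 in MCC CD69-lo (n = 3) and 1680 ± 432 in MCC CD69-hi (n = 3). At 6 h it stood at 79.9 ± 65.9 in NP (n = 2), 419 ± 85.4 in MCC CD69-lo (n = 2) and 1010 ± 222 in MCC CD69-hi (n = 3). At 24 h the means were 23.4 ± 27.2, 289 ± 10.3 and 208 ± 13.4 CPM (n = 3 each). Cd69 RNA was thus above NP in the CD69-lo fraction at each time. In NP 1 library at 6 h and another at 24 h carried much of the spread: NP 6 h replicate 1 had 126 CPM of Cd69 against 33.2 in the other, and NP 24 h replicate 1 had 54.9 against 8.28 and 7.14. Egr1 stood at 432 CPM in NP 6 h replicate 1 against 7.04, and at 121 in NP 24 h replicate 1 against 4.52 and 4.86.

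Transcripts of other cells were measured in every group. A list of 20 B-cell genes summed to 629.33 ± 119.03 plain CPM in NP at 1 h, 2439.4 ± 1824.65 in MCC CD69-lo, 4248.1 ± 1002.19 in MCC CD69-hi and 4640.03 ± 1358.33 in MCC+GP CD69-hi (n = 3 each). At 24 h the sum was 805.67 ± 142.61 in NP, 231.47 ± 84.71 in MCC CD69-hi and 1314.93 ± 464.01 in MCC CD69-lo and 3265.17 ± 534.94 in MCC+GP CD69-lo, where MHC class II genes summed to 5531.67 ± 324.8 against 1420.37 ± 175.01 in MCC CD69-lo. Myeloid and dendritic genes summed at 24 h to 371.9 plain CPM in NP, 1698.97 ± 195.79 in MCC CD69-lo and 8160.63 ± 632.46 in MCC+GP CD69-lo. At 6 h B-cell genes summed to 588.7 ± 196.72 plain CPM in NP (n = 2) and 1209.9 ± 469.68 in MCC CD69-hi (n = 3). MHC class II genes then summed to 272.65 ± 183.49 and 912 ± 437.7, and myeloid and dendritic genes to 328.5 ± 159.1 and 781.5 ± 294.24.

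**Figure D1:**
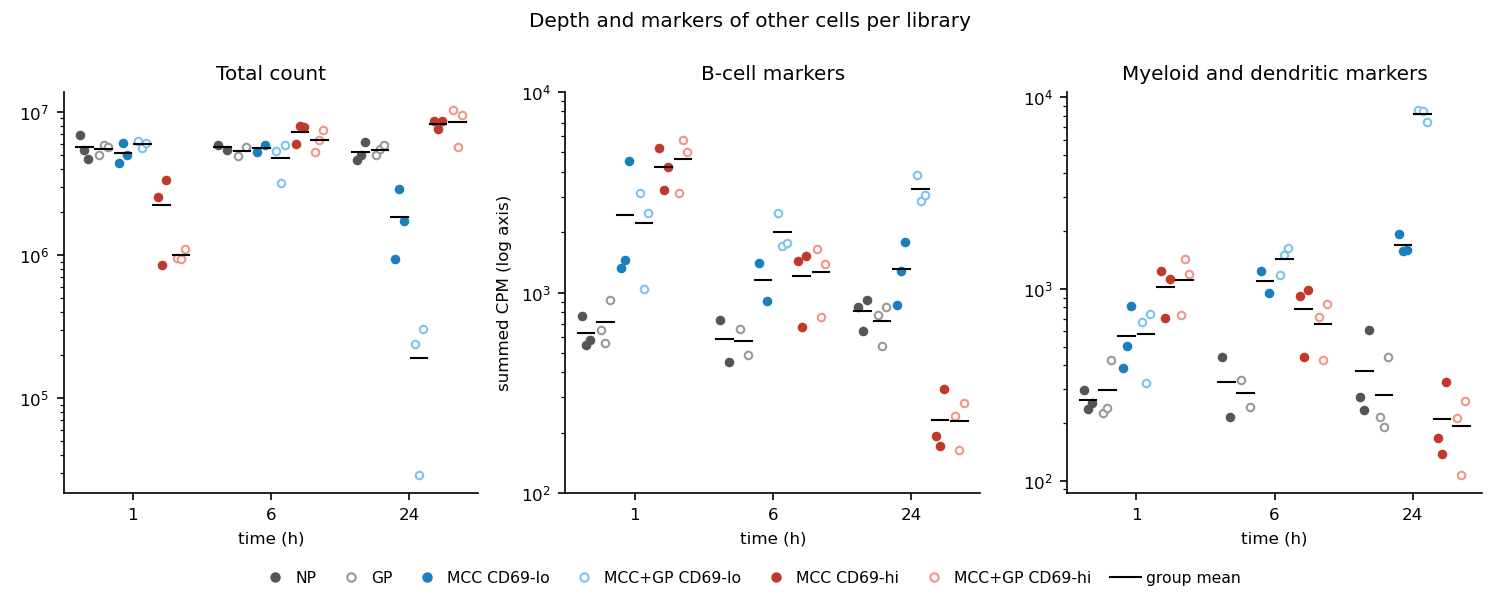
Total count per library, and the summed plain CPM of B-cell and of myeloid and dendritic genes, each on a log axis, by time in hours; points are libraries, black lines group means. The MCC+GP CD69-lo libraries of 24 h lie lowest in depth (29030 to 301455 counts) and highest in the myeloid sum.

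**Figure D2:**
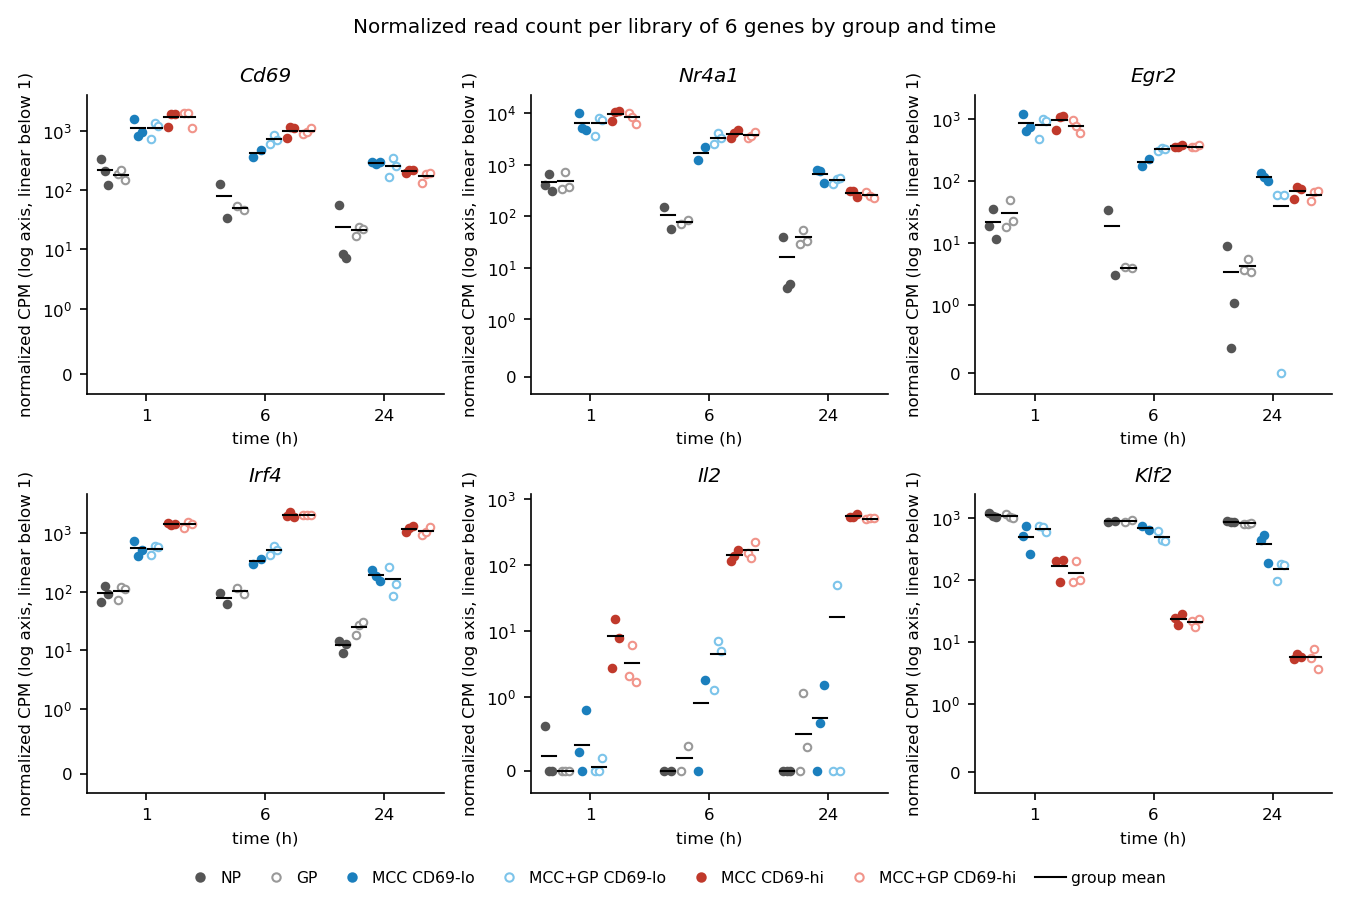
Normalized CPM of 6 genes per library by group and time in hours, on a log axis that is linear below 1 CPM; points are libraries, black lines group means. Il2 at 24 h averages 546 CPM in MCC CD69-hi and 0 in NP, while Klf2 averages 5.74 and 865 CPM.

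MCC CD69-hi against NP gives the response to the agonist peptide in cells that reached the CD69-high gate. At 1 h these libraries also held more RNA of other cells than NP. MHC class II genes summed to 4649.5 ± 1326.06 plain CPM against 475.83 ± 154.51, and myeloid and dendritic genes to 1024.1 ± 281.93 against 262.13 ± 29.95 (n = 3 each). Which cells expressed the genes that rose was not determined. Transcription factors that TCR signalling induces rose at 1 h. Nr4a1, which encodes the nuclear receptor Nur77, rose by 4.40 ± 0.53 to 9570 ± 2200 CPM from 453 ± 179 (adjusted p = 7.02e-08, n = 3 against 3). Egr3 rose by 6.76 ± 0.53 to 1780 ± 469 CPM, Egr1 by 5.67 ± 0.88 to 3970 ± 1240, and Egr2 by 5.47 ± 0.55 to 963 ± 250. Myc, a driver of cell growth, rose by 5.21 ± 0.27 to 1040 ± 143 CPM (adjusted p = 6.18e-19). Irf4, whose level follows signal strength, rose by 3.93 ± 0.25. Cd69 itself rose by 2.93 ± 0.47 (adjusted p = 1.08e-05), and over the alternatives its adjusted p ran from 1.18e-09 to 0.0672, the latter with only the compared groups and a plate-round block in the fit. Il2, the T cell growth factor, was low at 8.55 ± 6.24 CPM against 0.205 ± 0.355 and rose (adjusted p = 0.000639). The interleukin-2 receptor gene Il2ra rose by 3.05 ± 0.37 to 262 ± 39.6 CPM and Cd5, which encodes a dampening receptor, by 1.63 ± 0.32. Among the largest rises were the semaphorin gene Sema7a at 582 ± 33.9 CPM against 7.5 ± 0.555 and the stress factor Atf3 at 258 ± 71.3 against 3.25 ± 1.34. Genes of quiescence and lymph node traffic fell: Klf2 by 2.69 ± 0.32, the interleukin-7 receptor gene Il7r by 3.17 ± 0.34, and the sphingosine phosphate receptor genes S1pr1 by 3.07 ± 0.22 and S1pr4 by 3.33 ± 0.22. Mki67, a proliferation marker, rose by 2.32 ± 0.54 to 27.6 ± 11.6 CPM, and by 0.91 when B-cell RNA was a covariate (adjusted p = 0.481, range over the alternatives 5.12e-06 to 0.481).

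Over all genes tested at 1 h, 2131 rose and 2922 fell, of which 1585 and 1374 by over 2-fold. With RLE in place of TMM size factors 2555 rose and 2127 fell, so the balance between rising and falling depends on the normalization. The number called was 3348 with only the compared groups in the fit and 2458 with B-cell RNA as a covariate. Of 32 early TCR response genes 24 rose and 2 fell (25 and 3 adjusted over the list alone), with a median log2 fold change of 2.68 (camera adjusted p = 5.36e-21, 0.0231 with an estimated correlation). NFAT target genes, which answer to calcium, rose in 13 of 19 cases and fell in 1 (the same adjusted over the list alone; adjusted p = 0.00834 with an estimated correlation), with a median of 3.75, or 2.77 with members absent from NP set at their bound. Naive and quiescence genes fell in 26 of 30 cases and rose in 1 (27 and 1 adjusted over the list alone; adjusted p = 0.00145 with an estimated correlation). B-cell genes rose in 19 of 20 cases (19 adjusted over the list alone), among them Fcer2a at 204 ± 54.5 CPM against 14.3 ± 3.62. This list's call was lost with an estimated correlation (adjusted p = 0.175).

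At 6 h the cells expressed Il2 at 141 ± 27.4 CPM (n = 3), at least 554-fold above NP (n = 2), where no Il2 read was counted. Il2ra rose by 7.30 ± 0.54 to 1470 ± 281 CPM from 9.29 ± 1.03 (adjusted p = 7.18e-14) and Cd5 by 5.05 ± 0.44 to 426 ± 62.5. Nr4a1 rose by 5.25 ± 0.67 to 3970 ± 702 CPM, Egr2 by 4.28 ± 0.63 to 367 ± 18.9 and Irf4 by 4.73 ± 0.31 to 2070 ± 217. Egr1 stood at 479 ± 119 CPM against 220 ± 301 and did not pass in the fit of all libraries (1.12 ± 0.84, adjusted p = 0.29). It passed with only the compared groups and a plate-round block (adjusted p = 2.49e-17) and with a separate spread for each group (0.00192). With only the compared groups in the fit its adjusted p was 0.612. Without NP 6 h replicate 1 its difference was 6.07. The costimulatory receptor gene Tnfrsf9, which encodes 4-1BB, rose by 9.56 ± 0.85 to 531 ± 81.2 CPM. Klf2 fell by 5.22 ± 0.37 to 23.8 ± 4.7 CPM from 887 ± 20.7, and Dgka, which encodes a kinase that removes the TCR messenger diacylglycerol, fell by 4.86 ± 0.19 to 71.9 ± 15.9 from 2090 ± 257 (adjusted p = 9.06e-29). Genes that build ribosomes rose in 39 of 39 cases (39 adjusted over the list alone; median 3.35, camera adjusted p = 3.12e-34, 0.0108 with an estimated correlation), with Rrp12 at 349 ± 14.3 CPM against 10.1 ± 3.12. Genes of amino acid uptake and one-carbon metabolism rose in 30 of 31 cases (30 adjusted over the list alone; adjusted p = 0.0187 with an estimated correlation), with the serine synthesis gene Psat1 at 476 ± 40.3 against 10.5 ± 0.849. ERK feedback genes rose in 14 of 18 cases and fell in 1 (adjusted p = 0.0115 with an estimated correlation). The chaperone gene Hspd1 rose by 4.23 ± 0.27 and the fatty acid synthase gene Fasn by 3.14 ± 0.23. Type I interferon response genes fell in 33 of 39 cases with a median of negative 2.75 (camera adjusted p = 1.5e-12), a call lost with an estimated correlation (adjusted p = 0.379). The guanylate-binding gene Gbp4 fell by 4.46 ± 0.49 to 76.7 ± 20.6 CPM. In all 3989 genes rose and 4055 fell at 6 h.

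By 24 h Il2 had a mean of 546 ± 35.2 CPM, at least 3070-fold above NP (n = 3 each), where again none was counted. Irf4 rose by 6.62 ± 0.30 to 1180 ± 139 CPM from 12 ± 2.87 (adjusted p = 6.02e-24). Nr4a1 rose by 4.17 ± 0.56 to 285 ± 43.5 CPM. Klf2 fell by 7.23 ± 0.40 to 5.74 ± 0.537 CPM from 865 ± 13.5. Egr1 did not pass in the fit of all libraries here either (0.84 ± 0.76, adjusted p = 0.36). Without NP 24 h replicate 1 it differed by 4.02 (adjusted p = 0.000162). Over the other alternatives its adjusted p ran from 2.02e-08 to 0.787, and was 0.0113 with a separate spread for each group. Proliferation genes rose: Mki67 by 6.00 ± 0.51 to 358 ± 78.5 CPM, the replication gene Uhrf1 by 8.23 ± 0.37 to 809 ± 75.8, and the mitotic kinase gene Cdk1 by 7.28 ± 0.50 to 87.1 ± 10.9. The cell cycle list had 38 of 40 members up (38 adjusted over the list alone; median 4.48, camera adjusted p = 6.12e-20, 0.00145 with an estimated correlation). Metabolic genes rose with them. The glycolysis list had 19 of 24 up and 3 down (the same adjusted over the list alone; adjusted p = 0.0283 with an estimated correlation), with hexokinase Hk2 at 405 ± 10.1 CPM against 2.39 ± 0.935 and Gapdh at 2520 ± 145 against 141 ± 19.8. Cholesterol synthesis genes rose in 27 of 30 cases (28 adjusted over the list alone; adjusted p = 0.0424 with an estimated correlation), with Idi1 up by 4.59 ± 0.25. All 31 genes of oxidative phosphorylation rose (31 adjusted over the list alone), with Atp5b up by 2.61 ± 0.17, and this list's call was lost with an estimated correlation (adjusted p = 0.0842). The checkpoint gene Lag3 rose by 9.48 ± 0.63 to 230 ± 5.7 CPM, and the anti-apoptotic gene Bcl2l1 by 6.02 ± 0.29 to 397 ± 11.6. Interferon response genes of type I fell in 36 of 39 cases and rose in 2, with Ifit3 at 0.892 ± 0.408 CPM against 68.9 ± 27.0 (median negative 3.38, camera adjusted p = 2.01e-10, and 0.469 with an estimated correlation). Gata3, the main regulator of T helper 2 cells, fell by 1.23 ± 0.24. In all 5018 genes rose and 4938 fell at 24 h.

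**Figure D3:**
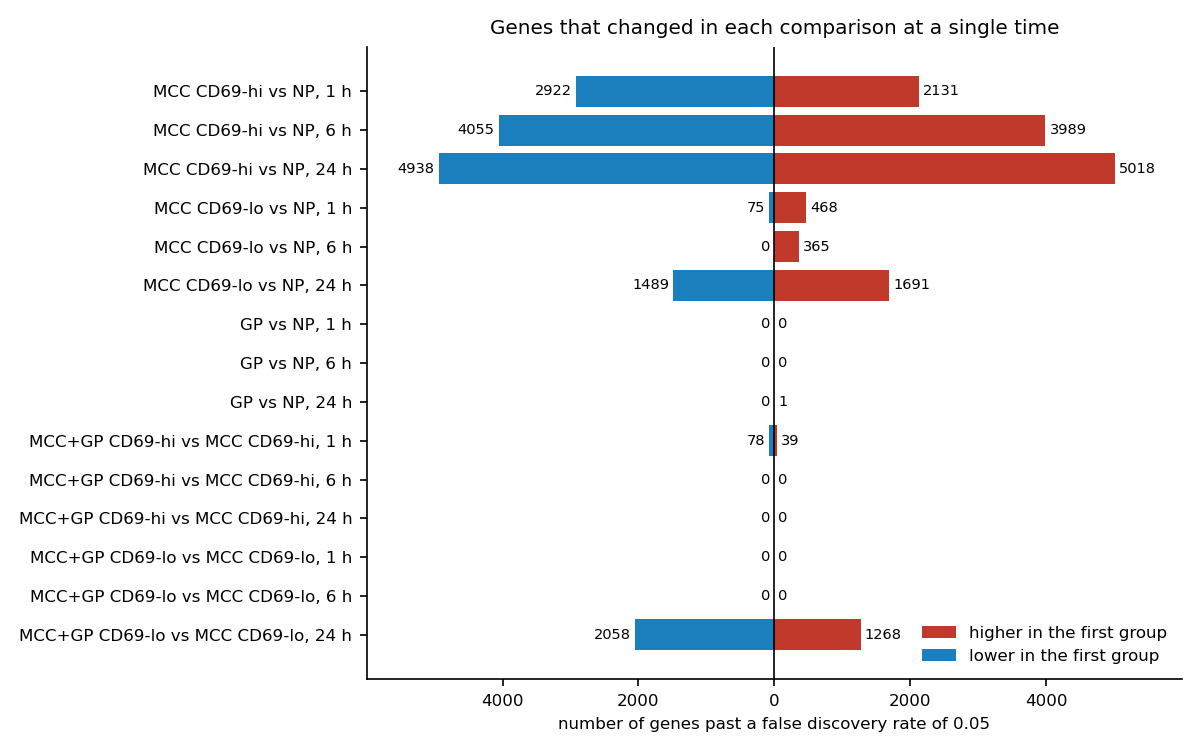
Number of genes past a false discovery rate of 0.05 in each comparison at a single time, with genes higher in the first group to the right and lower to the left. MCC CD69-hi against NP has 5018 rising and 4938 falling genes at 24 h, and MCC+GP CD69-hi against MCC CD69-hi has none at 6 and 24 h.

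MCC CD69-lo against NP asks how cells exposed to MCC that stayed CD69-low differ from cells with no peptide. At 1 h the early TCR genes rose in them as well: Nr4a1 by 3.85 ± 0.52 to 6510 ± 2950 CPM, Egr1 by 5.64 ± 0.88 to 3890 ± 1400, Egr2 by 5.34 ± 0.55 to 881 ± 317 and Myc by 3.70 ± 0.26 to 367 ± 97 (adjusted p from 3.14e-14 for Myc to 7.33e-05 for Egr1, n = 3 against 3). Cd69 rose by 2.35 ± 0.46 (adjusted p = 0.00181). The cytokine gene Tnf rose by 3.96 ± 0.50 to 222 ± 32.6 CPM, and Nfkbid, an NF-kB regulator, by 2.64 ± 0.27 to 1230 ± 509. Il2 was not raised (0.36 ± 0.42 CPM against 0.205 ± 0.355, adjusted p = 0.99), and Il2ra stood at 66.2 ± 16.9 CPM against 31.2 ± 11.8 (adjusted p = 0.121, range over the alternatives 5.72e-20 to 0.426, with DESeq2 and the fits with blocks within time calling it). Early TCR response genes rose in 22 of 32 cases (22 adjusted over the list alone; median 1.99, camera adjusted p = 3.44e-46, 0.00145 with an estimated correlation). B-cell genes rose in 17 of 20 cases (19 adjusted over the list alone; adjusted p = 0.0487 with an estimated correlation), as did 11 of 13 genes of MHC class II presentation (13 adjusted over the list alone; adjusted p = 0.0434 with an estimated correlation). Which cells expressed the induced genes at 1 h was not determined here either. In all 468 genes rose and 75 fell, and the number falling was 357 with DESeq2, 669 with only the compared groups and a plate-round block, and 248 with a separate spread for each group. The total of 543 became 266 without MCC CD69-lo replicate 3, which had the highest B-cell sum, and 327, 306 and 300 without NP replicate 1, 2 or 3. It was 1043 with DESeq2, 1885 with only the compared groups and a plate-round block, and 339 with B-cell RNA as a covariate.

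Among the largest rises in MCC CD69-lo at 6 h, the Notch ligand gene Dll4 rose by 7.89 ± 0.92 to 66.9 ± 16.9 CPM and the chemokine gene Ccl22 by 7.58 ± 1.01 to 377 ± 34.2 (adjusted p = 6.48e-07 and 6.76e-06, n = 2 against 2). Zbtb46, a transcription factor of classical dendritic cells, rose by 3.08 ± 0.45 to 35.3 ± 5.54 CPM from 4.13 ± 1.61. The myeloid and dendritic list had 5 of 26 members up (11 adjusted over the list alone; median 1.92, camera adjusted p = 7.24e-12), a call lost with an estimated correlation (adjusted p = 0.11). Genes that TCR signalling induces rose too. With dendritic cell genes up in the same libraries, which cells expressed the induced genes was not determined. Nr4a3 rose by 4.93 ± 0.41 to 1050 ± 421 CPM, Irf4 by 2.07 ± 0.29 to 328 ± 42.6 and Il2ra by 3.45 ± 0.49 to 101 ± 43.8. Nr4a1 rose by 4.02 ± 0.65 (adjusted p = 0.000125; 0.186 with only the compared groups in the fit, range over the alternatives 5.07e-10 to 0.425). Cd69 rose by 2.39 ± 0.57 (adjusted p = 0.0135), a call lost with only the compared groups (0.416, range over the alternatives 8.14e-05 to 0.561), without NP 6 h replicate 2 (0.561) and without MCC CD69-lo 6 h replicate 2 (0.115). Il2 stayed at 0.918 ± 1.3 CPM (adjusted p = 0.549), and Klf2 differed by less than its error (adjusted p = 0.892). The NF-kB target list had 15 of 25 members up (21 adjusted over the list alone; adjusted p = 0.00145 with an estimated correlation). Cytokines and chemokines rose in 9 of 27 cases (14 adjusted over the list alone; adjusted p = 0.00362 with an estimated correlation). Activation receptor genes rose in 10 of 23 (14 adjusted over the list alone; adjusted p = 0.0214 with an estimated correlation), and follicular helper genes in 4 of 13 (adjusted p = 0.0193 with an estimated correlation). For apoptosis genes, 4 of 24 rose (5 adjusted over the list alone), and the call was lost with an estimated correlation (adjusted p = 0.262). Heat shock genes rose in 1 of 20 cases (adjusted p = 0.572 with an estimated correlation). In all 365 genes rose and none fell in the edgeR fit of all libraries. The number falling was 99 with DESeq2, 33 with only the compared groups, 206 when a plate-round block was added to these, and 87 with a separate spread for each group. The total became 114 without NP replicate 2, 199 without NP replicate 1, 555 with a plate-round block and 1200 with only the compared groups and that block.

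At 24 h interferon genes rose in the CD69-lo fraction. All 28 interferon gamma response genes rose (28 adjusted over the list alone; median 2.02, camera adjusted p = 4.42e-30, 0.0358 with an estimated correlation), with Gbp2 up by 3.97 ± 0.61 to 1850 ± 253 CPM from 118 ± 51.2 (n = 3 each). The type I list had 36 of 39 up (37 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.0765), with the ubiquitin-like gene Isg15 at 85.4 ± 16.0 CPM against 8.31 ± 0.724. Genes that TCR signalling induces were raised: Nr4a1 rose by 5.37 ± 0.58 to 654 ± 179 CPM, Egr2 by 5.16 ± 0.64 to 117 ± 17.2 and Irf4 by 3.96 ± 0.27 to 188 ± 43. These libraries also held more RNA of other cells, with myeloid and dendritic genes at 1698.97 ± 195.79 plain CPM against 371.9 ± 205.3 in NP. Which cells expressed the induced genes was not determined. Cd69 rose by 3.65 ± 0.51 (adjusted p = 3.01e-06; range over the alternatives 3.3e-18 to 0.0629, the latter with only the compared groups in the fit). Il2 stayed at 0.725 ± 0.766 CPM (adjusted p = 0.187; range over the alternatives 0.0362, with DESeq2, to 0.454). Cytotoxic genes were among the largest rises, with granzyme B, Gzmb, at 115 ± 79.5 CPM, at least 645-fold above NP. The list of NK and CD8 T cells had 12 of 15 up and 1 down (adjusted p = 0.0179 with an estimated correlation), and the T helper 1 list 10 of 15 up (adjusted p = 0.0026 with an estimated correlation), with its regulator Tbx21 at 17.8 ± 10.4 CPM. Regulatory T genes rose in 9 of 14 cases (11 adjusted over the list alone; adjusted p = 0.0146 with an estimated correlation). Other cell markers rose with them, such as the plasmacytoid dendritic gene Siglech at 50.1 ± 36.0 CPM against 0.429 ± 0.458 and the neutrophil gene S100a9 at 57.7 ± 10.9 against 0.354 ± 0.614. Stromal, endothelial and erythroid genes rose in 2 of 13 cases (adjusted p = 0.523 with an estimated correlation). Of 34 genes of the TCR complex and proximal signalling 7 fell and none rose (10 and 1 adjusted over the list alone; median negative 0.147, camera adjusted p = 0.0146), a call lost with an estimated correlation (adjusted p = 0.587). Cd4 fell by 0.82 ± 0.19, Themis by 1.61 ± 0.19 and Il7r by 1.46 ± 0.31. In all 1691 genes rose and 1489 fell. The total of 3180 became 1981 without NP replicate 2, 1706 with only the compared groups in the fit, and 2093 without the first libraries of NP 6 h and NP 24 h.

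GP against NP asks whether the self-peptide alone changes gene expression. No panel gene passed in the fit of all libraries. At 1 h Nr4a1 stood at 473 ± 213 CPM with GP and 453 ± 179 without (0.06 ± 0.47, n = 3 against 3). Averaged over the 3 times, Nr4a1 differed by 0.31 with a 95% interval from negative 0.31 to 0.94, Cd69 by negative 0.37 (negative 0.96 to 0.23), Myc by 0.07 (negative 0.23 to 0.38), Klf2 by negative 0.05 (negative 0.42 to 0.32) and Cd5 by 0.38 (negative 0.05 to 0.80). Irf4 differed by 0.52 (0.22 to 0.83) and Il2ra by 0.64 (0.11 to 1.18), intervals for single genes, and neither passed over all genes (adjusted p = 1.0 for Irf4; range over the alternatives 0.049, without a filter on low counts, to 1.0). At 24 h Irf4 stood at 25 ± 6.21 CPM against 12 ± 2.87. Nr4a1 at 24 h was 38.7 ± 13.8 CPM against 16.2 ± 20.3 (1.29 ± 0.53, adjusted p = 1.0), and without the first libraries of NP 6 h and NP 24 h the difference was 3.10 with an adjusted p of 0.00914, the lowest of the alternatives, which ran up to 1.0. The only gene called was the epithelial anchor gene Lad1 at 24 h, with 15.3 ± 5.01 CPM against 1.55 ± 0.514 (3.25 ± 0.54, adjusted p = 0.0118). Its adjusted p ran up to 0.306 when 1 library was left out, and 5 of these 6 fits lost the call. It was 0.0621 with a plate-round-within-time block and 2.58e-05 with DESeq2, and the lowest over the alternatives was 2.48e-23.

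With edgeR no gene passed for GP at 1 h, at 6 h or in the mean over times, where 138, 126 and 199 genes had an unadjusted p under 0.05, and DESeq2 called 2, 0 and 0. At 24 h 190 genes had an unadjusted p under 0.05, and DESeq2 called 3. Each of these counts of unadjusted p is below a share of 0.05 of the 17211 genes tested. The fit of all libraries was thus conservative for GP. It estimated 1 dispersion per gene for all groups. Within a group the biological coefficient of variation ran from 8.2% (MCC CD69-hi 24 h) to 61.5% (MCC+GP CD69-lo 24 h). With only the GP and NP libraries of 24 h and a plate-round block in the fit, 54 genes rose and 71 fell, among them Irf4 (1.07, adjusted p = 1.03e-07) and Il2ra (1.42, adjusted p = 8.97e-06). Irf4 was also called without a filter on low counts (adjusted p = 0.00109), and over the other alternatives the adjusted p of both genes reached 1.0. The fit with only GP and NP of 24 h and a block had 879 of 11808 genes at an unadjusted p under 0.05. It has 2 residual degrees of freedom. Simulated changes in the 24 h comparison were recovered in 68% of genes at 2-fold and 90% at 4-fold, so smaller differences can be missed. Type I interferon response genes were lower at 24 h in 38 of 39 cases by the sign of their difference, with a median of negative 0.434 (camera adjusted p = 1.3e-22). In the fit of all libraries not 1 member passed on its own, over all genes or adjusted over the list alone, while 23 of 37 fell and none rose with only the compared groups and a plate-round block. In that fit 7 of 26 interferon gamma response genes fell too, as did 5 of 17 myeloid and dendritic genes (1 rose) and 2 of 12 MHC class II genes. Activation and costimulatory receptor genes rose there in 5 of 23 cases, and none fell. Every other list had at most 2 members rising, among them early TCR response genes with 2 of 28 up and none down. The call of the type I list in the fit of all libraries was lost with an estimated correlation (adjusted p = 0.148). At 6 h 38 of the 39 type I genes leaned the other way, with a median of 0.361 (camera adjusted p = 6.39e-09, 0.523 with an estimated correlation). Their sums in plate rounds 1 and 2 were 12242.8 and 6821 plain CPM with GP and 9120.2 and 6593.1 in NP. Most of the gap in the sum thus came from round 1. No list call for GP against NP held with an estimated correlation.

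MCC+GP CD69-hi against MCC CD69-hi asks whether the self-peptide modifies the response to the agonist in cells that reached the CD69-high gate. Both groups were gated on CD69 after treatment, so a change in the share of cells reaching the gate would not show here. The labels give no such share. The group means of the TCR response genes named here lay close together. Il2 at 6 h stood at 166 ± 48.4 CPM with GP and 141 ± 27.4 without (0.23 ± 0.32, n = 3 against 3), and at 24 h at 499 ± 6.49 and 546 ± 35.2 (negative 0.13 ± 0.32). Cd69 stood at 1710 ± 499 CPM against 1680 ± 432 at 1 h, and at 982 ± 135 against 1010 ± 222 at 6 h. At 24 h Cd69 was lower with GP in each plate round, at 108.09, 164.83 and 161.3 plain CPM against 159.61, 188.05 and 182.11. Nr4a1, Egr2, Il2, Il2ra and Myc were also lower with GP in each round of 24 h, by amounts that passed no test in the fit of all libraries. In the mean over times Cd69 differed by negative 0.10 (95% interval negative 0.62 to 0.42), Nr4a1 by negative 0.17 (negative 0.71 to 0.38), Myc by negative 0.07 (negative 0.33 to 0.19), Irf4 by negative 0.05 (negative 0.31 to 0.21), Il2ra by negative 0.04 (negative 0.43 to 0.35) and Il2 by negative 0.33 (negative 1.05 to 0.38). At 1 h some low-abundance genes were called. The phosphoglucomutase gene Pgm2 fell by 4.19 ± 0.65 to 0.636 ± 0.562 CPM from 12.2 ± 2.94 (adjusted p = 0.000198), and the collagen hydroxylase gene P3h1 fell by 4.13 ± 0.74 to 0.71 ± 1.23 from 13.1 ± 5.86 (adjusted p = 0.00174). Both means with GP lie under 0.97 CPM, the level of 3 counts in MCC+GP CD69-hi at 1 h, so the size of these falls is uncertain. Both genes had an adjusted p of 0.966 with a separate spread for each group, and of 5.87e-05 (Pgm2) and 0.000178 (P3h1) at the other end of the alternatives. The copine gene Cpne9 rose by 4.03 ± 0.89 to 15.1 ± 7.39 CPM from 0.759 ± 1.06 (adjusted p = 0.0199), and lost its call without MCC CD69-hi replicate 2 (0.0539) or 3 (0.0926), with a range over the alternatives of 0.00186 to 0.966. In the mean over times Elmo2 and Pgm2 fell, by 0.66 and 1.39 (adjusted p = 0.0155 each; over the alternatives 0.00136 to 0.986 for Elmo2 and 0.0073 to 0.986 for Pgm2, and 0.0571 for Elmo2 with a plate-round block). Elmo2 lost its call without MCC CD69-hi 1 h replicate 1 (0.063), MCC CD69-hi 6 h replicate 3 (0.0545) or MCC+GP CD69-hi 6 h replicate 2 (0.0639). Pgm2 lost it without MCC CD69-hi 1 h replicate 3 (0.0712), MCC+GP CD69-hi 1 h replicate 2 (0.105), or MCC+GP CD69-hi 6 h replicate 2 (0.0639) or 3 (0.0598).

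At 1 h 39 genes rose and 78 fell. With RLE size factors 53 rose and 34 fell. The number was 353 with DESeq2, 177 without a filter on low counts, 270 without the 3 MCC+GP CD69-lo libraries of 24 h, 29 with the deeper MCC CD69-hi libraries thinned, 7 with only the compared groups and a plate-round block, and 0 with only the compared groups or with a separate spread for each group. Without a single library it was 65 (MCC CD69-hi replicate 2), 54 (MCC CD69-hi replicate 3), 238 (MCC+GP CD69-hi replicate 1) or 205 (MCC+GP CD69-hi replicate 3). With edgeR no gene passed at 6 or 24 h, where 168 and 123 genes had an unadjusted p under 0.05 and DESeq2 called 0 and 3. Both counts of unadjusted p are below a share of 0.05 of the 17211 genes tested. With only the compared groups and a plate-round block 55 genes passed at 24 h and 40 in the mean over times, against 0 and 2 in the fit of all libraries. At 24 h 1195 of 11421 genes had an unadjusted p under 0.05 with that block. Simulated 2-fold changes were recovered in 56% of genes at 1 h and 79% at 24 h, and 4-fold changes in 84% and 94%. Cell cycle genes leaned upward at 24 h in 38 of 40 cases with a median of 0.186 (camera adjusted p = 5.93e-12, 0.0161 with an estimated correlation, 0.0579 with fry), while no member passed alone, over all genes or adjusted over the list alone. Mki67 in it stood at 421 ± 45.4 CPM against 358 ± 78.5. Inhibitory receptor genes leaned downward at 1 h with a median of negative 0.228 (adjusted p = 0.129 with an estimated correlation, 0.00659 with fry), and so did early TCR response genes with negative 0.252 (camera adjusted p = 0.00805, 0.699 with an estimated correlation, 0.119 with a plate-round block).

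MCC+GP CD69-lo against MCC CD69-lo puts the same question to cells that stayed CD69-low. At 1 h Cd69 stood at 1100 ± 330 CPM against 1120 ± 414 (negative 0.03 ± 0.44, n = 3 against 3). At 6 h (n = 3 against 2) the TCR target genes had higher means with GP, and none passed in the fit of all libraries. Nr4a1 stood at 3310 ± 784 CPM against 1700 ± 683 (0.96 ± 0.53, adjusted p = 0.897), Myc at 426 ± 110 against 220 ± 77.5 (0.95 ± 0.26, adjusted p = 0.796) and Cd69 at 716 ± 125 against 419 ± 85.4 (0.77 ± 0.50, adjusted p = 0.904). Myc had an adjusted p of 0.00607 without a filter on low counts and 0.0347 with only the compared groups and a plate-round block, where Nr4a1 had 0.0236, and over the alternatives both reached 1.0. ERK feedback genes leaned upward at 6 h in 16 of 18 cases with a median of 0.592 (adjusted p = 0.0221 with an estimated correlation). The early TCR list did so in 27 of 32 cases with a median of 0.596 and 3 members passing adjusted over the list alone (camera adjusted p = 9.08e-10, 0.179 with an estimated correlation), and genes of amino acid uptake and one-carbon metabolism in 29 of 31 cases with 7 members adjusted over the list alone (adjusted p = 0.0925 with an estimated correlation). All 20 B-cell genes leaned the same way with a median of 0.846 (adjusted p = 0.432 with an estimated correlation). With edgeR no gene passed at 1 or 6 h, where 123 and 971 had an unadjusted p under 0.05 and DESeq2 called 1 and 22. At 6 h the number was 8 without a filter on low counts, 8 with only the compared groups and a plate-round block, 33 without MCC+GP CD69-lo replicate 1 and 1 without MCC CD69-lo replicate 1. Simulated 2-fold changes were recovered in 71% of genes at 6 h and 4-fold changes in 95%.

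At 24 h T cell genes were lower in MCC+GP CD69-lo than in MCC CD69-lo, and genes of myeloid and dendritic cells higher (n = 3 each). The T cell factor genes Tcf7 and Lef1 fell by 2.16 ± 0.21 and 2.10 ± 0.24, with Tcf7 at 240 ± 141 CPM against 1240 ± 205 (adjusted p = 1.58e-10). With only the compared groups and a plate-round block Lef1 lost its call (negative 1.16, adjusted p = 1.0). The CD3 chain gene Cd3d fell by 2.15 ± 0.35 to 39.5 ± 40.3 CPM from 221 ± 19.1 (adjusted p = 1.25e-05; 0.178 with a separate spread for each group, range over the alternatives 3.93e-13 to 1.0). Tyrobp, which encodes a myeloid adaptor, rose by 2.79 ± 0.59 to 170 ± 63.2 CPM from 24.1 ± 15.6, and Irf8, a transcription factor of dendritic cells, by 2.01 ± 0.41 to 1030 ± 418 (adjusted p = 0.0664 and 0.169 with a separate spread for each group; highest over the alternatives 0.648 and 0.169). Shtn1 rose by 5.94 ± 0.90 to 69.9 ± 44.2 CPM from 1.27 ± 1.44 (adjusted p = 1.81e-06; 4.75e-11 to 0.123 over the alternatives, the latter with only the compared groups and a plate-round block). Nr4a1 and Cd69 passed no test in the fit of all libraries, with differences of negative 0.4 and negative 0.31 (adjusted p = 0.614 and 0.714), which does not show that they were equal. Cd69 stood at 256 ± 90.9 CPM against 289 ± 10.3. Genes of the TCR complex and proximal signalling fell in 21 of 34 cases and rose in 1 (23 and 1 adjusted over the list alone; median negative 1.31, adjusted p = 0.0392 with an estimated correlation). Naive and quiescence genes fell in 23 of 30 cases (adjusted p = 0.0122 with an estimated correlation). Myeloid and dendritic genes rose in 14 of 26 cases and fell in 1 (19 and 2 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.523). In all 1268 genes rose and 2058 fell, or 1739 and 1309 with RLE size factors, and 765 and 1668 with B-cell RNA as a covariate. The total of 3326 was 531 with only the compared groups in the fit, 8 when a plate-round block was added to these, and 91 with a separate spread for each group. Simulated 2-fold changes were recovered in 38% of genes and 4-fold changes in 75%, with 17 false calls in 130. The simulated groups had equal spread. The real ones had a biological coefficient of variation of 61.5% (MCC+GP CD69-lo) and 21.6% (MCC CD69-lo), so these rates need not hold for them. In the mean over times 607 genes rose and 1285 fell (831 and 867 with RLE, 387 and 1014 with B-cell RNA as a covariate), Tcf7 by 0.81 ± 0.11. With the mean of 1 and 6 h only, no gene passed in edgeR, 510 had an unadjusted p under 0.05, and Tcf7 differed by negative 0.14.

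Whether GP acts differently in activated and in resting cells was tested as the difference between its effects in MCC CD69-hi and in NP cells, averaged over times. Irf4 had a difference of negative 0.57 ± 0.20 (95% interval negative 0.97 to negative 0.17, adjusted p = 1.0), Cd69 of 0.27 (negative 0.53 to 1.06), Nr4a1 of negative 0.48 (negative 1.31 to 0.35) and Myc of negative 0.14 (negative 0.54 to 0.26). No gene passed with edgeR, 648 had an unadjusted p under 0.05, and DESeq2 called 2. Inhibitory receptor and anergy genes had a median of negative 0.135 (camera adjusted p = 0.00235), a call lost with an estimated correlation (adjusted p = 0.065), with 1 member lower adjusted over the list alone.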

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

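The tests of differences between times were planned, while the splits of the libraries and the tests of spread, B-cell RNA, depth, myeloid RNA, a swap and carried-over cells were chosen after the results had been seen, and the gene set changed over 8-fold was added after the result of the 2-fold set.

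Within each comparison, a test asked which genes differed between times. For MCC CD69-hi against NP the difference changed from 1 h to 6 h in 5140 genes (2894 higher, 2246 lower) and from 1 h to 24 h in 7755 (4410 higher, 3345 lower). For MCC CD69-lo against NP these numbers were 12 and 574. For MCC+GP CD69-hi against MCC CD69-hi they were 11 and 8. For MCC+GP CD69-lo against MCC CD69-lo 1847 genes differed between 1 h and 24 h (522 higher, 1325 lower). With edgeR, the tool run for these tests, no gene differed between 1 h and 6 h there (480 at an unadjusted p under 0.05), nor for GP against NP at 6 h or 24 h against 1 h (155 and 190), and DESeq2 was not run on these.

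The libraries of each comparison were also split in other ways into groups of the same sizes. Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. There the real split and the highest of the others gave 5053 and 8 genes for MCC CD69-hi against NP at 1 h, 9956 and 0 at 24 h, 543 and 0 for MCC CD69-lo against NP at 1 h, and 3180 and 23 at 24 h, so 1 of 10 splits gave as many each time. They gave 0 and 0 for GP against NP at 1 h (10 of 10 splits), 1 and 0 at 24 h (1 of 10), 0 and 1 for MCC+GP CD69-hi against MCC CD69-hi at 6 h and 0 and 0 at 24 h (10 of 10 each), and 0 and 20 for MCC+GP CD69-lo against MCC CD69-lo at 1 h (10 of 10). Where the real split gave 0 genes, every split gives at least as many, so these shares decide nothing. Of 100 splits within times, all 100 gave as many genes as the real one for GP against NP in the mean over times (0, highest other 3). The same held for the difference between the effects of GP (0, highest other 2). With a real count of 0 this outcome was fixed in advance, so it decides nothing. For MCC+GP CD69-hi against MCC CD69-hi in the mean over times 24 of 100 did (2, highest other 7). Chance cannot be excluded for that comparison in the fit of all libraries. The splits did not follow the plate rounds, so differences between rounds entered them. With only the compared groups and a plate-round block, a fit that was not split, these means had 0, 3 and 40 genes in that order (edgeR, 479 at an unadjusted p under 0.05 for the 0, and DESeq2 called 0). For MCC+GP CD69-lo against MCC CD69-lo in the mean over times 2 of 100 splits gave as many as the real 1892, with 2051 in the highest other. The 4 draws that left the 24 h groups whole gave 933 to 2051 genes and the other 95 at most 180, so this count rests on the 10 splits of 24 h, which are too few for a share under 0.05.

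At 1 h 117 genes differed between MCC+GP CD69-hi and MCC CD69-hi, while 4 of the 10 splits gave as many and the highest other split 177. With B-cell RNA as a covariate 108 of the 117 were called, while the same covariate took MCC CD69-hi against NP at 1 h from 5053 genes to 2458, which argues against B-cell RNA in unequal amounts as the whole cause. With a separate spread for each group 0 genes passed with limma, and the biological coefficient of variation was 24.5% in MCC+GP CD69-hi and 18.1% in MCC CD69-hi, so unequal spread between the groups may account for the calls. An effect of GP on genes of low abundance also stays open.

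At 24 h 3326 genes differed between MCC+GP CD69-lo and MCC CD69-lo, with 592 in the highest other of 10 splits. RNA of myeloid and dendritic cells in place of T-cell RNA may account for a part: genes of the TCR complex had a median of -1.31 while myeloid genes rose, with Irf8 at 1030 ± 418 CPM against 272 ± 66.7 and Tyrobp at 170 ± 63.2 against 24.1 ± 15.6, and while a sort of T cells would remove free myeloid cells, the labels name no marker of it other than CD69. Of 27 of the 28 myeloid genes (Itgam, whose symbol is repeated in the table, left out), 9 exceeded 5 CPM in NP at 24 h and 2 stand in another list. Other sums were higher in plain CPM, B-cell genes at 3265.17 ± 534.94 against 1314.93 ± 464.01 and NK and CD8 genes at 585.6 to 1151.1 against 216.7 to 417.6. TMM factors of 1.326, 2.135 and 1.277 in MCC+GP CD69-lo and 1.126, 1.077 and 1.144 in MCC CD69-lo were not applied to these sums. Applying them would narrow the gaps, most for replicate 2 with 29030 counts, so a separation of these sums need not hold. Unequal spread between the groups may account for another part, since 91 genes passed with a separate spread for each group, a fit in which 117 of 211 simulated calls were false. The simulated groups had equal spread, so that false share need not hold for the real ones. GP 24 h libraries thinned to these depths differed from NP in 0 genes with edgeR (506 at an unadjusted p under 0.05; DESeq2 was not run), but thinning does not stand for libraries made from little RNA, so low depth alone cannot be told apart from the group.

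The first NP library of 6 h and the first of 24 h, which are separate samples, stood apart, with Nr4a1 at 153 CPM against 55.4 at 6 h, and at 39.6 against 4.14 and 4.86 at 24 h. A swap with a GP library of 24 h would leave a GP library at the NP level, while the lowest GP library had 28.4 CPM of Nr4a1. For MCC CD69-lo cells in the first NP 6 h library, the 98 genes over 2-fold higher in such cells needed a median share of 5.41% (quartiles 0.309 to 9.82) against 5.94% for Nr4a1, 15.7% for Egr2 and 24.2% for Cd69, and the 34 genes over 8-fold needed 3.64%, so such cells may account for a part, although Il2ra stood at 8.56 CPM against 15.5 expected. For MCC CD69-hi cells the 2-fold and 8-fold sets needed 0.856% and 0.494% at 6 h, where Nr4a1 needed 2.5%, and -0.158% and -0.122% at 24 h, where it needed 12.5%; at 24 h this, with Il2ra at 4.82 CPM against 113 expected, argues against them, and at 6 h the quartiles of the 8-fold set (-0.452 to 2.14) and Il2ra and Il2 (8.56 and 0 CPM against 46.5 and 3.53) go against them, while those of the 2-fold set (-2.02 to 4.92) and Irf4 (95.5 CPM against 110 expected) leave them open. MCC CD69-lo cells in the 24 h library needed 0.481% in both sets against 5.4% for Nr4a1, where the quartiles of the 8-fold set (-0.773 to 2.7) go against them and those of the 2-fold set (-3.41 to 5.66) leave them open, and no biological explanation was tested.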

How the results depend on the processing

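RLE, no filter, DESeq2, only the compared groups, the replicate block and leaving libraries out were planned, and the other 8 alternatives were chosen after results had been seen.

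The report names 90 results of a gene in a comparison as past the threshold, many genes more than once, and these kept their direction in every alternative that tested them, single libraries left out included. The genes of the comparisons added later were not run under the alternatives. With RLE all 90 kept their call, 89 did with DESeq2, without a filter and with the replicate block by plate round. With only the compared groups 82 of 87 did, 77 of 87 when a plate-round block was added to these, and 82 of 90 with a separate spread for each group. In all 16 of their 544 results with a library left out lost the call. Of 188 list calls, 182 held with RLE, 176 with the replicate block, 117 with fry and 47 with an estimated correlation. The early TCR list in MCC+GP CD69-lo against MCC CD69-lo at 1 h reversed with the block, from a median of 0.029 (adjusted p = 0.0376) to -0.051 (0.534; the cause was not tested). RLE moved the median gene by 0.138 in MCC CD69-hi against NP at 1 h, -0.155 at 24 h, 0.101 in MCC+GP CD69-hi against MCC CD69-hi at 1 h and 0.217 in MCC+GP CD69-lo against MCC CD69-lo at 24 h. No total of genes called moved by over 1.5 times with RLE, while falling genes went from 78 to 34 in MCC+GP CD69-hi against MCC CD69-hi at 1 h, from 2058 to 1309 in MCC+GP CD69-lo against MCC CD69-lo at 24 h, and from 0 to 1 in MCC CD69-lo against NP at 6 h.

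Other alternatives moved counts of genes by more than 1.5 times, and the cause was not tested. Without a filter GP against NP had 5 genes at 24 h and 1 in the mean (from 1 and 0), MCC+GP CD69-hi against MCC CD69-hi 177 at 1 h (from 117), and MCC+GP CD69-lo against MCC CD69-lo 8 at 6 h (from 0). With DESeq2 the numbers were 2 at 1 h and 3 at 24 h for GP, 353, 3 and 27 for MCC+GP CD69-hi at 1 h, 24 h and the mean (from 117, 0 and 2), 1 and 22 for MCC+GP CD69-lo at 1 h and 6 h (from 0), 1043 and 630 for MCC CD69-lo against NP at 1 h and 6 h (from 543 and 365), and 2 for the difference between the effects of GP (from 0).

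With only the compared groups, which also changes the genes that pass the filter (7881 for MCC+GP CD69-lo at 24 h, from 17211), MCC CD69-hi against NP at 1 h had 3348 genes (from 5053), MCC+GP CD69-hi 0 at 1 h and 0 in the mean with edgeR (265 and 1009 at an unadjusted p under 0.05), MCC+GP CD69-lo 531 at 24 h and 672 in the mean (from 3326 and 1892), and MCC CD69-lo against NP 590 at 6 h and 1706 at 24 h (from 365 and 3180). With the plate-round block added to that, GP had 125 at 24 h, MCC+GP CD69-hi 7 at 1 h, 55 at 24 h and 40 in the mean, MCC+GP CD69-lo 8 at 6 h, 8 at 24 h and 484 in the mean, MCC CD69-lo against NP 1885, 1200 and 1806 at 1, 6 and 24 h, and the difference between the effects of GP 3.

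The replicate block by plate round gave 555 for MCC CD69-lo against NP at 6 h and 1 for MCC+GP CD69-hi in the mean, and moved no other total by over 1.5 times, while rising genes in MCC+GP CD69-hi against MCC CD69-hi at 1 h went from 39 to 23 and falling genes in MCC CD69-lo against NP at 6 h from 0 to 4. Within time it gave 661 and 1 for these, 0 for GP at 24 h (edgeR, 290 at an unadjusted p under 0.05) and 75 for MCC+GP CD69-hi at 1 h. With B-cell RNA as a covariate MCC CD69-hi against NP had 2458 at 1 h and MCC CD69-lo 339. A separate spread for each group gave 0 for MCC+GP CD69-hi at 1 h and in the mean with limma (866 and 736 at an unadjusted p under 0.05; DESeq2 353 and 27), 91 and 130 for MCC+GP CD69-lo at 24 h and in the mean, and 669 for MCC CD69-lo against NP at 6 h. Without the first NP libraries of 6 h and 24 h GP had 2 at 24 h, and MCC CD69-lo 192 at 6 h and 2093 at 24 h. Without the 3 shallowest libraries MCC+GP CD69-hi had 270 at 1 h, and with the deeper libraries thinned 29. The mean of 1 and 6 h only gave 0 for MCC+GP CD69-lo with edgeR, with 510 at an unadjusted p under 0.05.

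With a library left out, MCC CD69-hi against NP ran from 3875 to 4235, 6443 to 7541 and 9184 to 9339 at 1, 6 and 24 h, and MCC CD69-lo from 266 to 564, 114 to 266 and 1981 to 2981. GP against NP ran from 0 to 1 at 24 h and stayed at 0 elsewhere. MCC+GP CD69-hi ran from 54 to 238 at 1 h and 0 to 8 in the mean, and MCC+GP CD69-lo from 0 to 33 at 6 h, 2376 to 3162 at 24 h and 1367 to 2160 in the mean. Where this left 1 library in a group, that library was taken to vary like the other groups. Of the 5 comparisons simulated, MCC+GP CD69-lo against MCC CD69-lo at 24 h had the lowest recovery of 2-fold changes, 38% with edgeR against 56% to 79% in the others. The simulation kept the real depths and gave all groups the same dispersion, so unequal spread did not enter this recovery.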

Other observations

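The comparisons in this part were chosen after the results of the others had been seen.

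The CD69-hi and CD69-lo fractions of MCC cells were also compared with each other. Il2 was at 141 ± 27.4 CPM in CD69-hi and 0.918 ± 1.3 in CD69-lo at 6 h (n = 3 against 2), and at 546 ± 35.2 and 0.725 ± 0.766 at 24 h (n = 3 each). Fosb, an AP-1 factor, fell by 4.89 ± 0.54 in CD69-hi at 6 h, to 21 CPM from 616. All 39 ribosome biogenesis genes were higher in CD69-hi at 6 h and 39 at 24 h (adjusted p = 0.00881 and 0.0262 with an estimated correlation), and 38 of 40 cell cycle genes at 24 h (0.00214). All 39 type I interferon response genes were lower in CD69-hi at 24 h (camera adjusted p = 1.3e-21), a call lost with an estimated correlation (0.12). Genes of other cells were lower there as well: 19 of 20 B-cell genes, 21 of 26 myeloid and dendritic, 12 of 13 MHC class II, 11 of 15 NK and CD8, and 8 of 13 stromal genes, calls also lost with an estimated correlation (0.127 to 0.57). At 1 h the B-cell, myeloid and MHC class II lists leaned the other way, with 2 B-cell genes, 4 myeloid and dendritic and no MHC class II genes past the threshold (camera adjusted p = 1.72e-06, 3.03e-05 and 8.02e-05; 0.349, 0.292 and 0.349 with an estimated correlation). The hexokinase gene Hk2 stood at 405 CPM against 8.85 at 24 h.

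Cells without peptide differed between times. From 1 h to 6 h the guanylate-binding gene Gbp2 rose by 2.55 ± 0.61 to 965 ± 429 CPM from 164 ± 83.7, and 21 of 28 interferon gamma response genes rose (23 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). From 6 h to 24 h Gbp2 fell by 3.03 to 118 CPM, and 17 of the 28 fell (24 adjusted over the list alone; adjusted p = 0.0262 with an estimated correlation). Nr4a3 stood at 656 CPM at 1 h, 34.3 at 6 h and 10.2 at 24 h, and Fosl2 at 1110, 167 and 7.36. From 1 h to 24 h 19 of 32 early TCR response genes fell and 1 rose (22 and 1 adjusted over the list alone; adjusted p = 0.0753 with an estimated correlation). In all 1339 genes rose and 1506 fell from 1 h to 6 h, and 240 rose and 266 fell from 6 h to 24 h.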
